A study of Mus musculus with 4 samples.

How the data were processed

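RNA-seq of cultured mouse bone marrow macrophages was analysed in 4 libraries. Per the labels' protocols, wild-type marrow cells were grown for 7 days with 20 ng/ml MCSF, with medium changed every 48 h. M0 cells stayed unstimulated, and M1 cells received LPS and IFN-γ for the last 24 h. The labels do not say whether MCSF was kept in the M1 medium. Total RNA was extracted with Trizol, treated with DNase and depleted of ribosomal RNA by RNase H or Ribo-Zero before fragmentation and cDNA synthesis, per the labels' protocols.

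The deposited values are counts of reads per gene symbol, made with featureCounts of Subread 2.0.1 on mm10 per the submitters' processing notes. Those notes also name DESeq2 1.30.1 in R 4.0.4. They do not give the annotation, the strand setting or any gene filter, so counts of genes that overlap others on the opposite strand are uncertain. Each library lists the same 18256 symbols, of which 943 had no count. Symbols were matched to the RefSeq annotation of GRCm38.p6, the assembly that mm10 names, and 18226 (99.8%) were found. Mitochondrial genes carry RefSeq symbols there (ND1 for mt-Nd1), and these aliases were written after the symbols had been seen. Library totals were 18987705, 15921466, 17838606 and 17633945 counts for M0 replicates 1 and 2 and M1 replicates 1 and 2. A level of 3 counts corresponds to 0.144, 0.174, 0.185 and 0.185 CPM in the same order, so lower levels are not told apart from 0.

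Genes were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 12966 and removed 5290. TMM scaling factors were 1.10, 1.08, 0.911 and 0.922. M1 was compared with M0 by the edgeR quasi-likelihood test (estimateDisp, glmQLFit, glmQLFTest; group only, no block) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The common dispersion was 0.0118, a biological coefficient of variation of 10.9%, with 2 residual degrees of freedom. CPM was computed from the counts on library totals times TMM factors and is given as mean ± SD of 2 libraries. Log2 fold changes are fitted M1 over M0 values. Where a group had no count, the fold is given as a bound with that group at 3 counts. Where it had 1 to 3 counts, the ratio of group counts over group depth is given with an exact binomial 95% interval, which covers counting error only. Fold rules of log2 1 and 2 were applied to the fitted values of called genes.

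The comparison, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule names the 12 largest rises and 12 largest falls among called genes with at least 10 CPM in the higher group and no overlap of libraries between groups. It adds fixed hallmark genes, 2 of which are not analysed here. For each list it takes up to 4 called members with the largest change and up to 2 called in the direction opposite to most, and single members that did not pass are given with values only. The text prints some of these genes, leaving out list members whose call was lost when a library was left out. ND1, ND4L, Lars2, Mki67 and Camp are kept with values from the full and the reduced fits. Outside the rule 29 genes were chosen after their values were seen: H2-Aa, H2-Ab1, H2-Eb1, Irf8, Adgre1, Fth1, Apoe, Ngp, Ltf, S100a9, Csf3r, Col1a1, Ccr2, ND1, ND6, CYTB and members of the symbol families of the closing section. Of these Irf8 and some family members are not printed elsewhere.

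The 40 lists held 877 genes, 842 of them in the files. They cover proinflammatory cytokines, chemokines, antiviral interferon-stimulated genes, GTPases induced by interferon-gamma, MHC class I and class II presentation, costimulation, nitric oxide and arginine metabolism, alternative activation, macrophage identity, negative feedback, pattern recognition, inflammasome and cell death. They also cover glycolysis, the TCA cycle with oxidative phosphorylation, fatty acid oxidation, cholesterol synthesis and efflux, eicosanoids, iron, NADPH oxidase and antioxidants, complement, scavenger receptors, lysosome, adhesion, unfolded protein response, immediate early and heat shock genes and cell cycle. The others are mitochondrial transcripts, ribosomal proteins, nuclear RNAs and markers of neutrophils, T and NK cells, B and plasma cells, erythroid cells with megakaryocytes, dendritic cells, mast cells, stroma, osteoclasts and monocytes. Lists with at least 5 tested genes were tested with camera of limma 3.58.1 on the edgeR fit at its preset correlation of 0.01, with adjustment over the 37 lists. Counts of called members are also given with p adjusted over the list alone. Genes can stand in more than 1 list.

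Alternatives were relative log expression and upper-quartile factors, library totals, DESeq2 1.42.0, limma-voom, no low-count filter, a stricter filter (1 CPM in 2 libraries and 50 counts in total), the replicate number as a block, each library left out, libraries thinned to the smallest total, glmTreat and a log2 2 rule. For lists they were an estimated correlation, fry, camera on ranks, relative log expression factors, no filter, the block and each library left out. Library totals for lists were added after seeing the data, as was a scan of 353 symbol families of at least 5 tested genes. With a library left out, the lone library of its group is assumed to vary like the other group.

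The pipeline was tested on simulated data of 12663 genes with 200 changed and the lysosomal list raised by log2 1. It recovered 84% of genes changed by log2 1 and 99% at log2 2, with 82% for DESeq2, 84% for limma-voom and 84% with a block at log2 1. With 1 library left out it recovered 58%. In the first draw 24 unchanged genes were called, 10.1% of calls. The acceptance rule was then changed to the mean over 5 further draws, which was 4.65% (3.67% to 5.68%). Camera called 0 of 32 unchanged lists. Genes were simulated independently, so this does not show how often camera calls unchanged lists of correlated genes. The simulation also changed a far smaller share of genes than the 48.2% called here, so its rates may not carry over. To find genes with copies, GENCODE M21 transcripts of 314 genes were searched against all others with BLAST+ 2.17.0 (megablast), counting 95% identity over at least 30% of the transcript. Of 231 named genes 43 had such a copy.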

Results

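RNA was measured in macrophages grown from the bone marrow of wild-type mice, in 4 libraries that the labels place in 2 groups of 2. Bone marrow cells become macrophages in culture when given macrophage colony-stimulating factor (MCSF). M0 is the name for macrophages left unstimulated in MCSF. M1 is the name for macrophages stimulated with interferon-gamma (IFN-γ) and bacterial lipopolysaccharide (LPS), here at 20 and 100 ng/ml for 24 h. The M0 libraries held 18987705 and 15921466 counts over genes (replicates 1 and 2), and the M1 libraries 17838606 and 17633945. A count was present for 15523 and 15301 genes in M0 and for 14881 and 15088 in M1. At this depth 3 counts in a library correspond to 0.144 to 0.185 depth-scaled counts (CPM). Over the 12966 tested genes, the Spearman correlation was 0.994 between the M0 libraries, 0.993 between the M1 libraries and 0.893 to 0.902 between libraries of different groups. These are correlations across genes, which are not independent replicates. The libraries of a group differed by more than sampling noise, with a chi-square over degrees of freedom of 9.12 in M0 and 13.1 in M1. No label says that they came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

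The comparison asked how the transcriptome of stimulated M1 macrophages differed from that of unstimulated M0 macrophages. Most tested genes of the cytokine, chemokine, interferon-stimulated and MHC class I lists were higher in M1. The calls of these lists as groups are lost with an estimated correlation (adjusted p = 0.15 to 0.253). Mrc1, Cd28, Hpgd, Slco2b1 and many genes of the fatty acid oxidation and lipid uptake, scavenger and alternative activation lists were lower. Of 12966 tested genes, 3140 were higher and 3109 lower in M1 (edgeR quasi-likelihood test, adjusted p under 0.05). The M1 libraries lay on the same side of both M0 libraries for every called gene. That separation held for 74.95% of tested genes, against 33.3% expected by chance with 2 against 2. At least doubled were 1287 genes and at least halved 1504, and 665 and 650 passed a fold of 4. Many calls were lost without M0 replicate 1 or without M0 replicate 2, in fits that take the spread from the M1 libraries alone. The median log2 fold change of all genes moved by 0.00505 without M0 replicate 1 and by 0.00155 without M0 replicate 2. Scaling by library totals moved the median log2 fold change of all genes by -0.252 and gave 29.8% of calls higher instead of 50.2%. Upper-quartile scaling moved the median by -0.104.

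**Figure D1:**
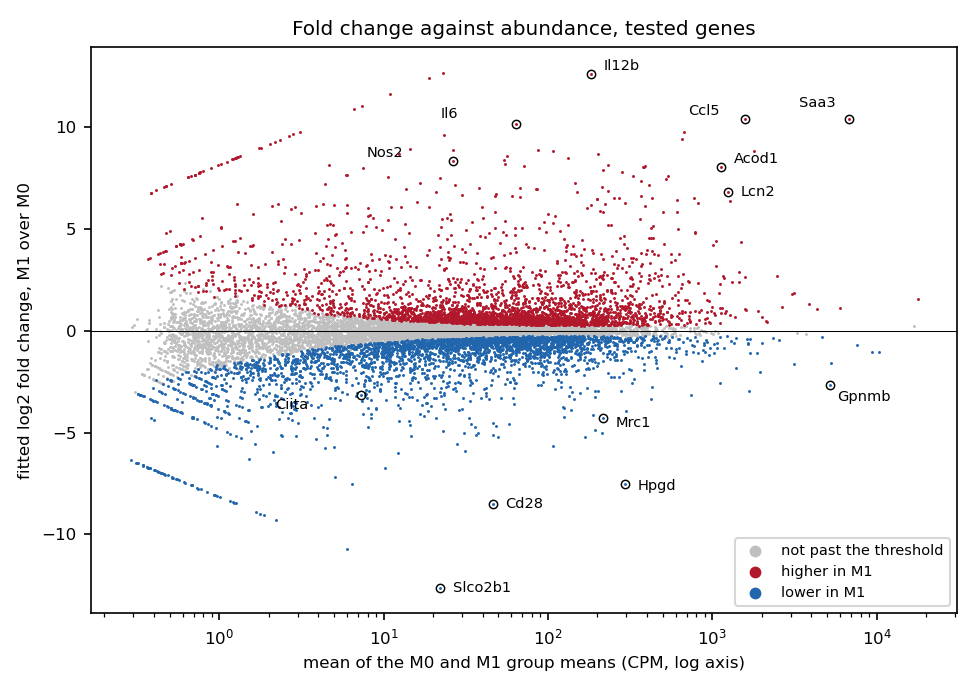
Each point is a tested gene, with the mean of the M0 and M1 group means in CPM on a log axis and the fitted log2 fold change of M1 over M0 on the other axis. Red points are the 3140 genes higher in M1, blue points the 3109 lower and grey points those that did not pass, and points in diagonal lines are genes with 0 or a few counts in a group, for which the fitted value is not a bound.

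Genes of cytokines and chemokines were among the largest rises. Transcripts of Il12b, the p40 subunit of interleukin-12 and interleukin-23 (chromosome 11, 44400063 to 44414677 in GRCm38.p6), reached 365 ± 53.9 CPM (SD, n = 2 libraries in each group here and throughout) against 2 counts over both M0 libraries, a ratio of 6945 (95% counting interval 1922 to 57360). Ccl12, a monocyte-attracting chemokine, had no count in M0 and 45.7 ± 14.9 CPM in M1, at least 580.4-fold higher when M0 is set at 3 counts over the group. On the same floor Csf3, which encodes granulocyte colony-stimulating factor, was at least 279-fold higher and Cxcl11 at least 478-fold higher. The RefSeq annotation of this build classes Cxcl11 as a transcribed pseudogene. Saa3, an acute-phase serum amyloid gene (chromosome 7, 46711998 to 46719615), rose from 10.4 ± 6.15 to 13523 ± 655 CPM, and Ccl5 (chromosome 11, 83525778 to 83530518) rose from 2.42 ± 0.509 to 3179.5 ± 614 CPM. Their log2 fold changes were 10.36 and 10.37 (adjusted p = 1.05e-09 and 5.24e-11). Il6 rose from 0.116 ± 0.164 to 128 ± 4.19 CPM (log2 fold change 10.15) and Ms4a4c from 1.57 ± 0.0125 to 1347 ± 191 CPM (9.73). Expression also rose for Slfn4, of the Schlafen family, from 1.86 ± 0.494 to 1298 ± 72.6 CPM (9.42). Il12a, the p35 subunit of interleukin-12, had 2 counts in M0 and 46.9 ± 0.803 CPM in M1, a ratio of 892 (95% counting interval 247 to 7375). The complement gene Cfb and the pseudogene Gm6553 were at least 187- and 168-fold higher, and both are uncertain because annotated genes share 81.7% and 100% of their transcripts. Single M0 libraries set the size of some of these folds. Il12b and Il12a had no count in M0 replicate 2, and Il6 had none in M0 replicate 1. Without M0 replicate 1 the log2 fold change of Il6 was 9.06, and without M0 replicate 2 it had no M0 count. Without M0 replicate 2 that of Saa3 was 11.11.

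Among the largest falls, Slco2b1, an organic anion transporter (chromosome 7, 99657804 to 99711340), had 44.3 ± 1.46 CPM in M0 and no count in M1, at least 478-fold lower. Shisa9 was at least 130.5-fold lower on the same floor. Cd28, best known as the costimulatory receptor of T cells (chromosome 1, 60746388 to 60773359), fell from 91.8 ± 6.41 to 0.246 ± 0.000101 CPM (log2 fold change -8.50, adjusted p = 2.66e-10). Hpgd, the enzyme that inactivates prostaglandins (chromosome 8, 56294552 to 56321046), fell from 582 ± 68.3 to 3.17 ± 0.741 CPM (-7.52, adjusted p = 1.13e-10). The chemokine receptor gene Cxcr4 fell from 210.4 ± 15.4 to 4.16 ± 0.0418 CPM (-5.66). So did the monoacylglycerol lipase gene Mgll from 61.1 ± 1.82 to 1.02 ± 0.566 CPM (-5.90) and the fatty acid binding protein gene Fabp4 from 96.8 ± 1.64 to 2.55 ± 0.565 CPM (-5.24). Mamdc2, Pcp4l1 and Nat8l fell with log2 fold changes of -5.54, -6.72 and -6.01. Cd207, the langerin gene, and Dkk2, a Wnt antagonist gene, had 2 counts each over the M1 libraries, all in M1 replicate 2, and M0-over-M1 ratios of 206 (95% counting interval 56.7 to 1705) and 157 (95% counting interval 43.2 to 1304). Without M1 replicate 2, Cd207 and Dkk2 had no M1 count. Without M1 replicate 1 their fitted log2 fold changes were -6.63 and -6.26, against -7.54 and -7.18 with all libraries. Leaving out M1 replicate 2 moved Mgll to -6.61 and Nat8l to -5.28, and leaving out M1 replicate 1 moved Nat8l to -7.55.

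Markers of activation that were fixed in advance separated the groups. Nos2, the inducible nitric oxide synthase (chromosome 11, 78920787 to 78960226), rose from 0.144 ± 0.204 to 52.7 ± 1.197 CPM (log2 fold change 8.33, adjusted p = 8.59e-09). Acod1, which makes itaconate, rose from 8.63 ± 1.15 to 2257 ± 21.1 CPM (8.03). Il1b rose from 8.17 ± 4.02 to 3596 ± 46.4 CPM (8.80), Tnf from 19.2 ± 5.203 to 309.9 ± 28.0 CPM (4.02). The interferon-induced chemokines Cxcl9 and Cxcl10 rose from 0.288 ± 0.407 to 108 ± 4.96 CPM (8.39) and from 5.67 ± 3.13 to 1069 ± 75.9 CPM (7.59). The costimulatory ligand gene Cd86 rose from 19.2 ± 0.825 to 83.9 ± 6.17 CPM (2.12). Mrc1, the mannose receptor (chromosome 2, 14229414 to 14332023), fell from 411 ± 10.99 to 20.7 ± 1.86 CPM (-4.31, adjusted p = 3.01e-10). Ciita, the class II transactivator (chromosome 16, 10480014 to 10531064), fell from 13.1 ± 0.0725 to 1.45 ± 0.218 CPM (-3.17) and Chil3 from 48.8 ± 3.59 to 25.3 ± 3.54 CPM (-0.95). Arg1, a marker of alternative activation, rose from 0.973 ± 0.0185 to 5.73 ± 1.48 CPM (2.55), as did Il10 from 1.04 ± 0.2503 to 5.42 ± 1.66 CPM (2.38). The MCSF receptor gene Csf1r did not pass, at 3403 ± 30.4 CPM in M0 and 3102 ± 239 CPM in M1 (log2 fold change -0.13, adjusted p = 0.266). It passed as lower when libraries were scaled by their totals. The proliferation marker Mki67 was lower (-0.44, adjusted p = 0.00557), a call lost without M0 replicate 1 (adjusted p = 0.122) and without M0 replicate 2 (0.0787). Without M0 replicate 2, Nos2 stood at 7.48, Cxcl9 at 7.53, Cxcl10 at 8.27 and Il1b at 9.40. Without M0 replicate 1 neither Nos2 nor Cxcl9 had a count in M0.

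**Figure D2:**
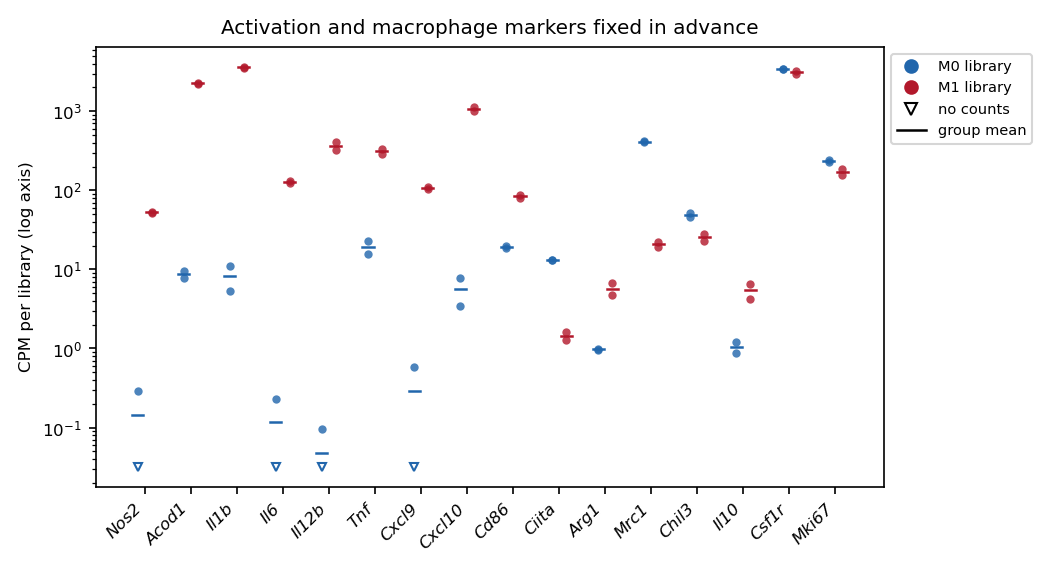
Each point is 1 library's CPM on a log axis for a gene fixed in advance, blue for M0 and red for M1, with a bar at the group mean and an open triangle for a library with no count. Acod1 stands at 8.63 ± 1.15 CPM in M0 and 2257 ± 21.1 CPM in M1, Mrc1 at 411 ± 10.99 CPM and 20.7 ± 1.86 CPM, and the Csf1r libraries of both groups lie close together on this axis.

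Of 16 tested proinflammatory cytokine genes, 15 rose, 0 fell and 1 did not pass (15 higher and 0 lower adjusted over the list alone). The median log2 fold change was 5.25, and the list was higher than other genes by camera (adjusted p = 2.06e-35, and adjusted p = 0.15 with an estimated correlation). Of 20 chemokine genes, 17 rose and 2 fell (1 not passed, 17 and 2 adjusted over the list alone), with a median of 5.00, or 4.52 with genes absent from M0 at their bound (camera adjusted p = 5.01e-21, and adjusted p = 0.253 with an estimated correlation). Ccl6 went the other way, from 120.1 ± 32.9 to 39.4 ± 1.71 CPM (-1.61). Transcripts that restrain inflammation rose alongside: of 24 genes of negative feedback, 19 rose, 1 fell and 4 did not pass (19 and 1 adjusted over the list alone, camera adjusted p = 6.52e-21). That list had an adjusted p = 0.15 with an estimated correlation. Il1rn, the interleukin-1 receptor antagonist, rose from 20.9 ± 1.94 to 1614 ± 102 CPM (6.27). The cytokine signalling inhibitors Socs3 and Socs1 rose from 12.8 ± 0.147 to 474 ± 26.4 CPM (5.21) and from 0.704 ± 0.317 to 26.5 ± 1.14 CPM (5.25).

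All 33 tested antiviral interferon-stimulated genes rose (33 adjusted over the list alone), with a median log2 fold change of 4.26 (camera adjusted p = 3.99e-100, and adjusted p = 0.15 with an estimated correlation). Irf7, a transcription factor of the interferon response, rose from 16.6 ± 1.48 to 1530.1 ± 36.2 CPM (6.53). Usp18, which removes ISG15 from proteins, rose from 5.85 ± 1.56 to 533 ± 61.1 CPM (6.52). Isg15 itself rose by 7.35 on the log2 scale and is uncertain because an annotated pseudogene shares 63.8% of its transcript. The 18 GTPase genes induced by interferon-gamma, which act against intracellular pathogens, all rose (18 adjusted over the list alone). Their median was 6.17, or 5.86 with genes absent from M0 at their bound (camera adjusted p = 6.97e-47, and adjusted p = 0.15 with an estimated correlation). Gbp4 rose from 0.356 ± 0.175 to 109 ± 2.698 CPM (8.18, or 8.83 without M0 replicate 1). Counts of Gbp6, Gbp10 and Gbp11 are uncertain because of near-identical family members. All 23 genes of MHC class I presentation rose as well (23 adjusted over the list alone), with a median of 2.67 (camera adjusted p = 9.3e-38, and adjusted p = 0.15 with an estimated correlation). H2-Q4, a nonclassical class I gene, rose from 32.6 ± 1.94 to 485 ± 39.6 CPM (3.90). H2-Q6, H2-Q7 and H2-T22, with log2 fold changes of 7.58, 8.15 and 4.53, share sequence with other class I genes and are uncertain.

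Genes of MHC class II presentation moved both ways. Of 13 tested, 3 rose, 6 fell and 4 did not pass (4 and 6 adjusted over the list alone). The median was -0.20 and the mean 0.16, and camera placed the list lower without a call (adjusted p = 0.231). The class II chain genes H2-Aa and H2-Eb1 fell, from 163 ± 16.3 to 86.3 ± 2.402 CPM (-0.91) and from 131 ± 24.6 to 56.5 ± 1.63 CPM (-1.22). H2-Ab1 rose from 111 ± 28.6 to 199 ± 7.93 CPM (0.84, adjusted p = 0.000803). Cd74, the invariant chain, did not pass, at 521 ± 106 CPM in M0 and 453 ± 15.9 CPM in M1 (adjusted p = 0.223). Lgmn, a lysosomal protease, fell from 992 ± 92.1 to 300.4 ± 24.9 CPM (-1.72). H2-Ob rose from 0.385 ± 0.134 to 4.53 ± 0.481 CPM (3.51). Of 12 tested markers of dendritic cells, which carry much class II, 4 rose, 6 fell and 2 did not pass (4 and 6 adjusted over the list alone, camera adjusted p = 0.505). Among them Ccr7 had no count in M0 and 4.68 ± 0.437 CPM in M1, at least 59.4-fold higher. Cd209a had 1.21 ± 0.0878 CPM in M0 and no count in M1, at least 13.1-fold lower. Of 12 costimulatory and checkpoint ligand genes, 8 rose, 2 fell and 2 did not pass (8 and 2 adjusted over the list alone, camera adjusted p = 2.98e-06, and adjusted p = 0.163 with an estimated correlation). Cd274, which encodes PD-L1, rose from 36.4 ± 0.667 to 839 ± 63.3 CPM (4.53), Cd40 from 7.24 ± 1.63 to 139.9 ± 8.85 CPM (4.26) and Lgals9 from 55.7 ± 6.06 to 629 ± 7.83 CPM (3.50). The checkpoint gene Vsir fell from 405 ± 9.74 to 199 ± 2.69 CPM (-1.03).

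**Figure D3:**
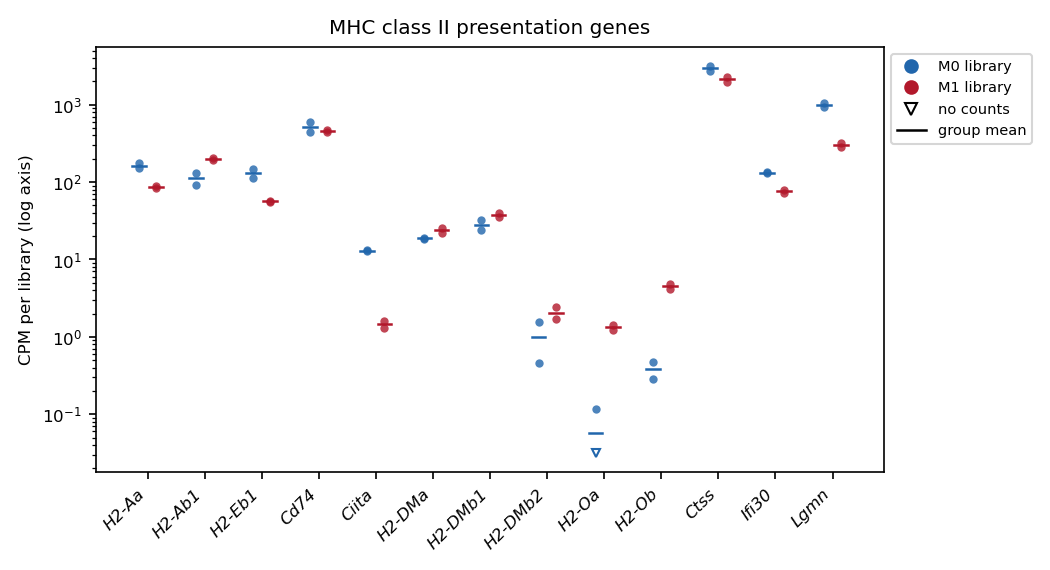
Each point is 1 library's CPM on a log axis for the 13 genes of the class II list, blue for M0 and red for M1, with a bar at the group mean and an open triangle for no count. H2-Ab1 lies higher in M1 while H2-Aa, H2-Eb1, Ciita and Lgmn lie lower.

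Genes of nitric oxide, arginine and itaconate metabolism rose in 9 of 13 cases, with 0 falls (4 not passed, 9 and 0 adjusted over the list alone, camera adjusted p = 1.71e-09, and adjusted p = 0.15 with an estimated correlation). With library totals 7 rose and 2 fell. The arginine transporter gene Slc7a2 rose from 54.3 ± 4.78 to 1511 ± 157 CPM (4.80). Of 24 alternative activation markers, 16 fell, 6 rose and 2 did not pass (17 lower and 6 higher adjusted over the list alone). Their median was -1.40 (camera adjusted p = 5.85e-05, and adjusted p = 0.217 with an estimated correlation), and 14 of the list's genes stand in another list too. Pparg, a lipid-sensing nuclear receptor, fell from 70.7 ± 2.65 to 2.03 ± 1.31 CPM (-5.12, or -5.98 without M1 replicate 2). Members that rose included Arg1, Il10 and the chemokine gene Ccl22, from 0.536 ± 0.554 to 17.5 ± 1.44 CPM (5.09, or 4.22 and 6.85 without M0 replicates 1 and 2). Macrophage identity genes split, with 9 of 22 higher, 10 lower and 3 not past the threshold (10 and 10 adjusted over the list alone). Their median was -0.14 and their mean 0.07, and camera placed them higher without a call (adjusted p = 0.861). The Fc receptor gene Fcgr1 rose from 98.5 ± 22.8 to 1029 ± 74.04 CPM (3.39) and Adgre1, which encodes F4/80, from 1370 ± 2.99 to 4881 ± 212 CPM (1.83). Gpnmb fell from 8994 ± 80.4 to 1421 ± 71.9 CPM (-2.66), the lipid receptor gene Trem2 from 747 ± 53.4 to 109 ± 13.1 CPM (-2.77). The myeloid transcription factor gene Cebpa fell from 358 ± 9.27 to 45.8 ± 14.3 CPM (-2.96). Lysozyme, Lyz2, did not pass at 15513 ± 1524 CPM in M0 and 18086 ± 679.9 CPM in M1 (adjusted p = 0.0814).

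Pathogen sensors rose more often than they fell. Of 28 pattern recognition receptor and adaptor genes, 17 rose, 4 fell and 7 did not pass (17 and 5 adjusted over the list alone, camera adjusted p = 0.00214, and adjusted p = 0.323 with an estimated correlation). With library totals 15 were higher and 10 lower. Clec4e, the Mincle receptor, rose from 30.5 ± 0.3096 to 2525 ± 192 CPM (6.37) and Nod2, a sensor of bacterial peptidoglycan, from 3.16 ± 0.209 to 45.9 ± 2.59 CPM (3.85). Clec7a, the β-glucan receptor Dectin-1, fell from 558 ± 22.6 to 36.7 ± 2.32 CPM (-3.93). Tlr13, a sensor of bacterial ribosomal RNA, fell from 506 ± 35.8 to 132 ± 0.446 CPM (-1.94). Of 26 inflammasome and cell death genes, 18 rose, 3 fell and 5 did not pass (19 and 3 adjusted over the list alone, camera adjusted p = 5.49e-14, and adjusted p = 0.193 with an estimated correlation). The nucleic acid sensor gene Zbp1 rose from 4.48 ± 1.04 to 393 ± 11.8 CPM (6.47) and Mlkl, the executor of necroptosis, from 8.29 ± 1.81 to 119.7 ± 8.06 CPM (3.86). Nlrp1b fell from 33.8 ± 0.647 to 12.2 ± 1.65 CPM (-1.47). Bcl2a1a and Bcl2a1d rose too but belong to a family of near-identical copies and are uncertain.

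In carbon metabolism, glycolytic genes rose in 19 of 24 cases and fell in 2 (3 not passed, 19 and 2 adjusted over the list alone, median 1.02, camera adjusted p = 6.84e-06, and adjusted p = 0.163 with an estimated correlation). Pfkfb3, an activator of glycolysis, rose from 56.4 ± 1.82 to 376 ± 28.2 CPM (2.74), the hypoxia-inducible factor gene Hif1a from 138 ± 2.42 to 452 ± 28.5 CPM (1.72). The lactate exporter gene Slc16a3 rose from 45.2 ± 6.04 to 129 ± 15.9 CPM (1.51). Genes of the TCA cycle and oxidative phosphorylation were not called as a list (camera adjusted p = 0.505), with 19 of 41 higher and 4 lower (18 not passed, 19 and 4 adjusted over the list alone), a balance that turned to 5 higher and 8 lower with library totals. Without M0 replicate 2 the list was called higher (adjusted p = 0.02603), as it was by camera on ranks (0.0154). Idh1, the cytosolic isocitrate dehydrogenase, fell from 308 ± 20.9 to 91.2 ± 2.01 CPM (-1.76). Of 24 genes of fatty acid oxidation and lipid uptake, 15 fell, 1 rose and 8 did not pass (15 lower and 2 higher adjusted over the list alone, median -0.56, camera adjusted p = 2e-06, and adjusted p = 0.24 with an estimated correlation). The lysosomal lipase gene Lipa fell from 2969 ± 198 to 384 ± 5.37 CPM (-2.95). Genes of cholesterol synthesis were not called as a list (camera adjusted p = 0.389), with 3 of 24 higher and 8 lower (13 not passed, 3 and 8 adjusted over the list alone), or 0 and 11 with library totals. Dhcr7 fell from 41.03 ± 3.14 to 15.9 ± 2.95 CPM (-1.37). Cholesterol efflux and LXR target genes were not called either (adjusted p = 0.501), with 4 of 15 higher and 8 lower (3 not passed, 4 and 8 adjusted over the list alone). In that list Ch25h, which makes 25-hydroxycholesterol, rose from 1.59 ± 0.621 to 41.2 ± 1.11 CPM (4.72). Apoe, the lipid carrier, fell from 12638 ± 842 to 6202 ± 274 CPM (-1.03).

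Prostaglandin genes moved in opposite ways. Ptges and Ptgs2, which encode prostaglandin E synthase and cyclooxygenase-2, rose from 3.01 ± 1.404 to 758 ± 20.9 CPM (8.01) and from 14.02 ± 2.73 to 244 ± 10.7 CPM (4.13), while Hpgd fell as given above. The 19 tested eicosanoid genes held 8 rises and 10 falls (1 not passed, 8 and 10 adjusted over the list alone) and were not called as a list (adjusted p = 0.413). Iron handling genes held 8 rises and 8 falls among 17 (1 not passed, 8 and 8 adjusted over the list alone). Lcn2, the siderophore-binding lipocalin, rose from 21.9 ± 3.22 to 2458 ± 22.6 CPM (6.81), the ferritin heavy chain gene Fth1 from 8968 ± 1179 to 26502 ± 2512 CPM (1.56). Ceruloplasmin, Cp, rose from 4.49 ± 0.452 to 396 ± 33.4 CPM (6.46). Slc40a1, the iron exporter ferroportin, fell from 358 ± 7.87 to 20.1 ± 2.34 CPM (-4.16). Camera called the iron list higher (adjusted p = 0.0313, and adjusted p = 0.297 with an estimated correlation), with a median of 0.19 that turned to -0.07 with library totals. The iron call was lost without M0 replicate 1 (adjusted p = 0.412), without M0 replicate 2 (0.481) and on ranks (0.745). Of 20 NADPH oxidase and antioxidant genes, 15 rose and 5 fell (0 not passed, 15 and 5 adjusted over the list alone, camera adjusted p = 0.000128, and adjusted p = 0.297 with an estimated correlation). Sod2, the mitochondrial superoxide dismutase, rose from 95.1 ± 5.905 to 2002 ± 37.7 CPM (4.40). Catalase, Cat, fell from 581 ± 6.93 to 189.7 ± 0.2703 CPM (-1.61). Complement genes were not called as a list (adjusted p = 0.537), with 8 of 17 higher and 7 lower (2 not passed, 9 and 7 adjusted over the list alone), a balance that turned to 6 higher and 7 lower with library totals. C3, the central complement component, rose from 52.3 ± 7.81 to 1515 ± 172 CPM (4.86). The receptor gene C5ar2 fell from 14.4 ± 0.182 to 1.82 ± 0.1298 CPM (-2.98).

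Scavenger and efferocytosis receptor genes fell in 16 of 23 cases and rose in 3 (4 not passed, 16 lower and 3 higher adjusted over the list alone, median -0.87, camera adjusted p = 6.82e-07, and adjusted p = 0.217 with an estimated correlation). Gas6, a bridging ligand for apoptotic cells, fell from 327 ± 23.7 to 8.68 ± 1.39 CPM (-5.23). The scavenger receptor gene Marco went the other way, from 2.82 ± 2.98 to 298 ± 33.6 CPM (6.80, or 5.92 and 8.68 without M0 replicates 1 and 2). Of 32 lysosomal genes, 18 fell, 8 rose and 6 did not pass (18 lower and 8 higher adjusted over the list alone). Psap, the saposin precursor, fell from 7967 ± 288 to 2634 ± 39.2 CPM (-1.60) and Atp6v0d2, a proton pump subunit, from 373 ± 0.808 to 12.7 ± 1.05 CPM (-4.87). The cathepsin genes Ctsc and Ctsz rose from 348 ± 33.7 to 2544 ± 3.09 CPM (2.87) and from 509 ± 18.5 to 1395 ± 29.6 CPM (1.45). The lysosomal list was called lower (camera adjusted p = 0.0479, and adjusted p = 0.652 with an estimated correlation). It was not called without M0 replicate 2 (adjusted p = 0.133), without M1 replicate 1 (0.0528), without M1 replicate 2 (0.102) or on ranks (0.0812). Adhesion and matrix genes held 15 rises and 9 falls among 30 (6 not passed, 15 and 9 adjusted over the list alone). The collagenase gene Mmp13 rose from 10.9 ± 0.123 to 764 ± 15.6 CPM (6.13) and Tgfbi from 60.4 ± 11.4 to 822 ± 6.87 CPM (3.77). The integrin gene Itga6 fell from 258 ± 10.5 to 17.6 ± 1.34 CPM (-3.87). Camera called this list higher (adjusted p = 0.0096, and adjusted p = 0.59 with an estimated correlation) with a median of 0.19 that turned to -0.06 with library totals. The adhesion call was lost without M0 replicate 1 (adjusted p = 0.218), without M0 replicate 2 (0.196) and on ranks (0.325).

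Genes of the unfolded protein response rose in 14 of 22 cases and fell in 2 (6 not passed, 14 and 4 adjusted over the list alone), or 9 and 5 with library totals. The endoplasmic reticulum genes Creld2 and Manf rose from 26.2 ± 0.182 to 105 ± 4.83 CPM (2.00) and from 42.5 ± 5.198 to 129 ± 9.89 CPM (1.60). The stress transcription factor gene Atf3 fell from 274 ± 3.59 to 143 ± 17.2 CPM (-0.93). This list was called higher (camera adjusted p = 0.0311, and adjusted p = 0.297 with an estimated correlation), and not with library totals (adjusted p = 0.0628) or without M1 replicate 1 (0.0518). Immediate early and heat shock genes were not called as a list (adjusted p = 0.0969, or 0.0223 without M0 replicate 2 and 0.0406 on ranks), with 12 of 20 higher and 2 lower (6 not passed, 12 and 2 adjusted over the list alone), or 9 and 4 with library totals. Ier3 rose from 13.6 ± 2.38 to 104 ± 5.14 CPM (2.93) and Jun fell from 109 ± 9.27 to 45.1 ± 7.38 CPM (-1.27). Cell cycle genes were not called (adjusted p = 0.717), with 11 of 40 higher and 5 lower (24 not passed, 10 and 5 adjusted over the list alone), a balance that turned to 4 higher and 10 lower with library totals. The S-phase genes Rrm2 and Ccne1 rose by 0.86 and 0.88 on the log2 scale, and the mitotic motor gene Kif11 fell from 66.3 ± 2.25 to 42.3 ± 3.16 CPM (-0.65).

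All 12 tested transcripts of the mitochondrial genome fell (12 adjusted over the list alone), with a median of -1.10 (camera adjusted p = 0.000353, and adjusted p = 0.376 with an estimated correlation). They took 2.17% and 2.36% of the counts in M0 and 1.09% and 1.01% in M1 (replicates 1 and 2). CYTB fell from 2540.1 ± 327 to 1176 ± 221 CPM (-1.11) and ND1 from 2000.5 ± 329 to 1274 ± 233 CPM (-0.65). The ND1 call was lost without M0 replicate 2 (log2 fold change -0.47, adjusted p = 0.133). ND4L, the largest fall of the list at -1.54, lost its call without M0 replicate 1 (-1.24), M0 replicate 2 (-1.77) or M1 replicate 1 (-1.11). ND6 lies antisense to its neighbours and is uncertain because the strand of counting is not given. Of the others, 9 share sequence with annotated pseudogenes. Cytoplasmic ribosomal protein genes were not called as a list (adjusted p = 0.211, or 0.0155 and lower without M0 replicate 1), with 2 of 74 higher, 19 lower and 53 not past the threshold (0 and 15 adjusted over the list alone). With library totals 0 were higher and 33 lower. Of 75 searched, 64 share sequence with annotated copies, so their counts are uncertain. Among 5 tested genes of the list of nuclear-retained and small structural RNAs, 1 was higher and 1 lower (3 not passed, 1 and 1 adjusted over the list alone, camera adjusted p = 0.54). With library totals 0 were higher and 3 lower. The gene called higher was Lars2 (0.56), which encodes a mitochondrial tRNA synthetase and is not such an RNA. Its call was lost without M0 replicate 1 (0.47), M0 replicate 2 (0.66) or M1 replicate 2 (0.25). Neat1 fell from 584 ± 5.08 to 329 ± 33.7 CPM (-0.83) and Malat1 did not pass, at 585 ± 69.8 CPM in M0 and 469 ± 125 CPM in M1 (adjusted p = 0.118).

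Markers of other cell types that bone marrow culture could hold were measured as well. Of 15 tested neutrophil markers, 10 fell, 3 rose and 2 did not pass (10 lower and 3 higher adjusted over the list alone, camera adjusted p = 0.525, or 0.04796 without M0 replicate 1 and 0.0309 on ranks). The granule genes Ltf and Ngp fell from 35.4 ± 6.49 to 5.11 ± 0.5203 CPM (-2.79) and from 35.7 ± 5.63 to 7.91 ± 2.14 CPM (-2.17). S100a9 fell from 74.01 ± 1.92 to 28.8 ± 7.19 CPM (-1.36). The 3 that rose were Lcn2, given with the iron genes, Csf3r and Camp. Csf3r had a log2 fold change of 1.15 and is uncertain because of an annotated copy. Camp rose from 2.89 ± 0.0145 to 6.96 ± 0.177 CPM (1.27), a call lost without M0 replicate 1 (adjusted p = 0.0543). The summed CPM of the list was 406 in M0 and 2842 in M1, where Lcn2 alone stood at 2458 ± 22.6 CPM. Of 4 tested T and NK cell markers, 2 fell and 0 rose (2 not passed, 2 lower and 1 higher adjusted over the list alone). Il7r, the interleukin-7 receptor, fell from 237 ± 2.37 to 12.6 ± 4.97 CPM (-4.23) and Cd4 from 21.4 ± 0.144 to 4.74 ± 0.259 CPM (-2.18). Of 6 B and plasma cell markers, 3 fell and 1 rose (2 not passed, 3 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0969). The immunoglobulin gene Ighm fell from 139 ± 8.01 to 34.2 ± 2.903 CPM (-2.02). Stromal and endothelial markers held 6 rises and 7 falls among 14 (1 not passed, 6 and 7 adjusted over the list alone), with a median of -0.27 and a mean of 0.19 (camera lower, adjusted p = 0.537). The collagen gene Col1a1 fell from 309.8 ± 10.0 to 203 ± 14.9 CPM (-0.61). Osteoclast markers held 6 rises and 3 falls among 10 (1 not passed, 6 and 3 adjusted over the list alone, camera adjusted p = 0.525). Among them Acp5, the acid phosphatase TRAP, rose from 12.4 ± 1.73 to 105 ± 0.391 CPM (3.08). Monocyte and progenitor markers held 5 rises and 5 falls among 14 (4 not passed, 5 and 5 adjusted over the list alone, camera adjusted p = 0.0926). With library totals these became 5 rises and 6 falls, and camera called the list higher (adjusted p = 0.0447), as it did with no low-count filter (0.0336). The haptoglobin gene Hp rose from 5.21 ± 2.14 to 362 ± 19.96 CPM (6.14). The chemokine receptor gene Ccr2 fell from 41.5 ± 6.17 to 6.96 ± 0.955 CPM (-2.57). Of 4 tested erythroid and megakaryocyte markers 1 rose, 1 fell and 2 did not pass, and of 3 mast cell and basophil markers 1 rose, 0 fell and 2 did not pass, with the same counts adjusted over the list alone. Both lists and the T and NK list were too short for a list test.

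**Figure D4:**
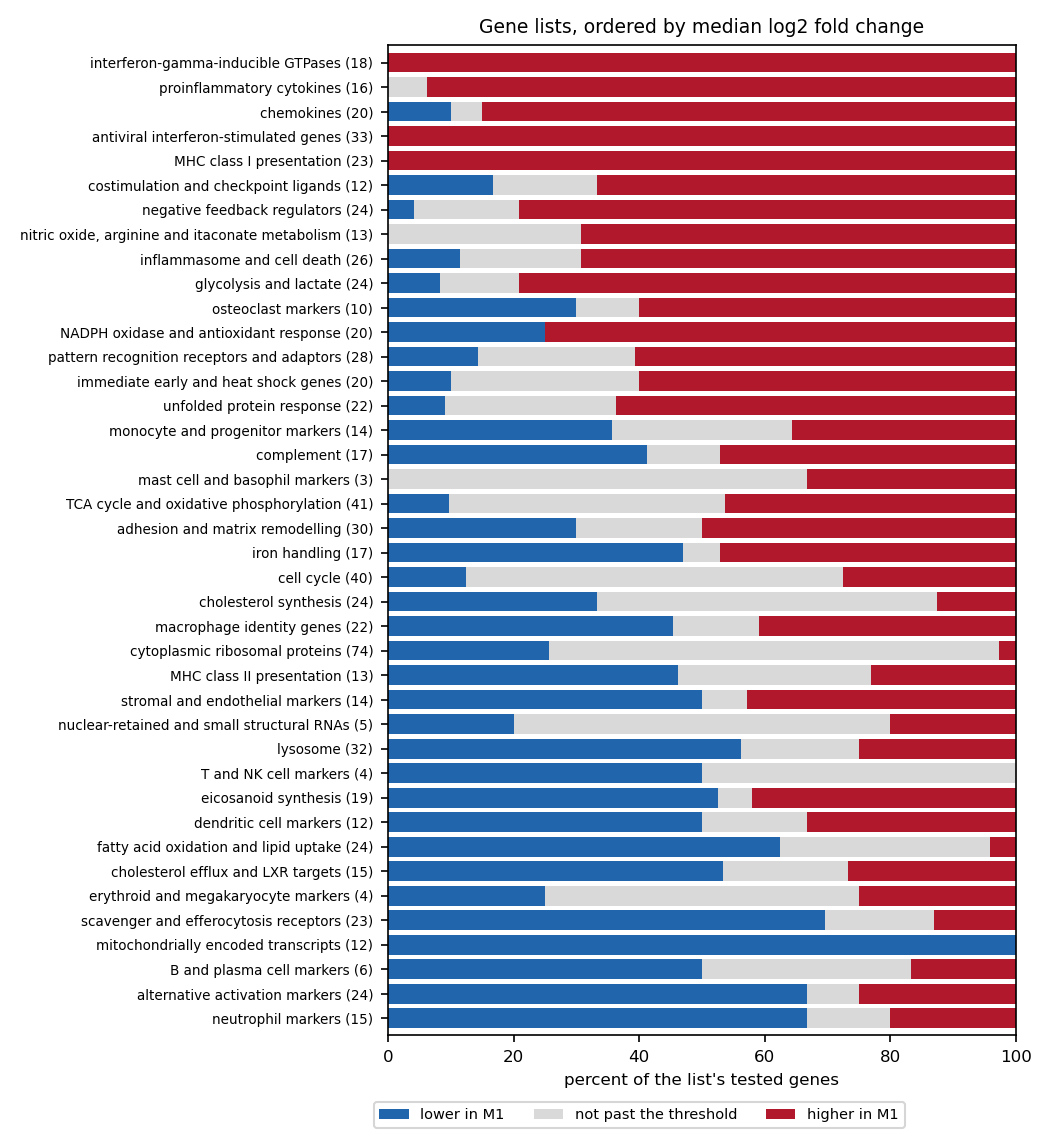
Each bar is a gene list fixed in advance, with the number of its tested genes in brackets, and shows the percent of those genes that were lower (blue), not past the threshold (grey) and higher (red) in M1, ordered by median log2 fold change. The GTPases, the antiviral genes and class I presentation are wholly red and the mitochondrial transcripts wholly blue, and with library totals the balance turns to lower for the TCA cycle, the cell cycle and complement.

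Of 37 lists tested with camera at its preset correlation of 0.01, 15 were higher and 5 lower. With the correlation estimated from these libraries on 2 residual degrees of freedom, camera called 0 of the 37. By that test 9 were higher and 0 lower at an unadjusted p under 0.05. Fry, which tests whether a list's genes move on balance one way without comparing them with other genes, called 18 higher and 7 lower.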

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

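Library totals for the gene lists were chosen after the result was seen, the other alternatives before. No gene called in both the edgeR fit and an alternative changed direction, and no named gene or list reversed. Relative log expression factors kept 99.7% of the 6249 calls, limma-voom 98.9%, thinning 97.7%, no low-count filter 97.7% and the stricter filter 97.0%. DESeq2 kept 91.5%, with 2932 genes higher and 2790 lower. Upper-quartile factors kept 91.5%, with 2607 higher and 3745 lower. With library totals 2024 genes were higher and 4776 lower, as the median log2 fold change of all genes moved by -0.252 from that with TMM factors. Which scaling is right was not tested. GlmTreat, which asks for a fold beyond 2 with its error, gave 872 genes doubled and 798 halved, and the log2 2 rule gave 665 and 650, both fewer by construction. Leaving out 1 library gave 1722 to 2889 genes higher, 1508 to 2858 lower, 1101 to 1285 doubled and 1001 to 1539 halved, with the lowest counts without an M0 library and fewer samples in each such fit. In a fit without an M0 library the spread came from the M1 pair. That pair had the larger chi-square over degrees of freedom, 13.1 against 9.12 in M0. Whether this caused the difference between leaving out M0 and M1 libraries was not tested. Lists ranged from 13 to 15 higher and from 4 to 7 lower in those fits. With an estimated correlation camera called 0 lists higher and 0 lower. For nitric oxide metabolism (-0.0748) and glycolysis (-0.0428) the estimate lay below the preset 0.01, and for chemokines (0.542) above it. A larger correlation therefore does not account for every lost call. The estimate rests on 2 residual degrees of freedom. With an estimated correlation camera also takes its p-values from a distribution on those 2 degrees of freedom. Small p-values are then hard to reach whatever the correlation. A lost call therefore does not show that a list or family is unchanged. Other causes were not tested. The replicate block gave 2957 genes higher, 2974 lower, 1282 doubled and 1466 halved, with 14 lists higher and 4 lower. Deviations of replicate 1 correlated at -0.0757 between M0 and M1 across genes, and 2 pairs do not show that shared numbers mark paired samples. Of 230 named genes tested, calls were lost by 8 with library totals (Csf1r gained one), 4 with upper-quartile factors, 4 with DESeq2, 2 with the block and 1 with thinning. They were lost by 32 without M0 replicate 1, 29 without M0 replicate 2, 12 without M1 replicate 1 and 6 without M1 replicate 2. The replicate block also ended the calls of the iron list (camera adjusted p = 0.0604), the lysosomal list (0.0651) and the unfolded protein response (0.0505), and it made the monocyte list called higher (0.0438). Fry also called higher the monocyte list (adjusted p = 0.0285), the osteoclast list (0.0211) and the immediate early list (0.0224), and called lower the B cell list (0.00311) and cholesterol efflux (0.0203). Depth limits values near the 3-count floor, where folds are bounds or wide ratios.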

Other observations

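Families of genes that share a symbol stem were scanned after the data had been seen. Interferon-activated Ifi genes stood out, with 16 of 18 higher in M1, 1 lower and a median log2 fold change of 4.85 (camera adjusted p = 8.16e-31). This call and every other family call given here is lost with an estimated correlation (adjusted p = 1 for each). On 2 residual degrees of freedom and over 353 families that test could hardly call any, so the losses do not count against a family. Ifi44 rose from 5.604 ± 2.16 to 498 ± 24.6 CPM (6.49), and Ifi208 and Ifi205 share sequence with other Ifi genes and are uncertain. Ifi44 and Ifi35 stand in the antiviral list as well, Ifi204 in the inflammasome list and Ifi30 in the class II list. All 8 tested Schlafen symbols rose, the pseudogene Slfn10-ps among them, with a median of 2.42 (adjusted p = 4.68e-16), Slfn8 from 60.6 ± 1.33 to 502 ± 7.59 CPM (3.05). All 5 Slamf receptor genes rose (adjusted p = 1.89e-07), Slamf8 from 17.03 ± 0.678 to 92.1 ± 7.003 CPM (2.44) and Slamf9 from 21.9 ± 0.246 to 274 ± 28.4 CPM (3.65). Parp genes split, 7 higher and 3 lower of 12 (adjusted p = 8.2e-05), and Parp14 stands in the antiviral list too. Torsin-related Tor genes rose in 6 of 7 cases (0.0304).

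Genes with proteasome symbols were higher beyond the immunoproteasome. All 10 Psmb genes were higher (median 1.28, adjusted p = 9.13e-07), as were all 6 Psme genes (0.00157), 12 of 14 Psmd genes (0.0304) and 8 of 9 Psma genes (0.0462, and 0.0648 by fry). With an estimated correlation each of these 4 families had an adjusted p = 1, which for the reason given above does not count against them. Of 7 Psmc genes 6 were higher, and that family was not called (adjusted p = 0.0692). The counts follow symbols, so they include Psme3ip1, which is not a subunit gene, and the pseudogene Psma5-ps. Psmb8, Psmb9, Psmb10, Psme1 and Psme2 stand in the class I list as well. These genes and Psme2b count in the Psmb and Psme tests, and no test was run without them. The other Psme genes, Psme3, Psme3ip1 and Psme4, rose by 0.35, 0.47 and 0.50 on the log2 scale. Psmb7 and Psmb5, which encode subunits of the constitutive proteasome, had log2 fold changes of 1.45 and 1.58. Both are uncertain, as the protein-coding gene Nek6 shares 35.1% of the Psmb7 transcript and an annotated pseudogene shares 88.4% of that of Psmb5. Of 353 families 10 were higher and 1 lower by camera at its preset correlation (not all are named here), and 0 with an estimated correlation (smallest adjusted p = 1).

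The tests of the 3 patterns that follow were all chosen after the result was seen. Class II genes moved apart, with Ciita, H2-Aa and H2-Eb1 lower and H2-Ab1 higher. Fewer class II-rich cells of another type would lower these genes together. H2-Ab1 lay above H2-Aa by a log2 difference of 1.75 (SE 0.184) and above H2-Eb1 by 2.05 (SE 0.200). These differences restate the calls that define the pattern, so they are no separate test of cell mixture. Sequence shared with another gene covers 0% of the H2-Ab1 transcript. Fewer such cells alone would not raise H2-Ab1, but a change of cell mixture beside another change stays open. Different regulation of these transcripts was not tested.

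All 12 tested mitochondrial transcripts fell, with log2 fold changes from -1.54 to -0.65. The value of -1.54 is that of ND4L, whose call was lost without M0 replicate 1 (-1.24), M0 replicate 2 (-1.77) or M1 replicate 1 (-1.11). Scaling of libraries may shift the list, and its highest median over 4 scalings was -1.09. The scalings tried moved the median of all genes by 0.00567, -0.104 and -0.252. They could not have brought the list to 0, so a larger error of scaling was not tested. The 3 genes with no annotated copy were ND1 (-0.65), ND6 (-1.09) and CYTB (-1.11), and the 9 with a copy had a median of -1.12. Shared sequence may explain little of the fall, but this rests mainly on CYTB. ND6 stays uncertain for want of the strand, and ND1 did not pass without M0 replicate 2 (log2 fold change -0.47, adjusted p = 0.133). Lower mitochondrial expression on stimulation and a difference in RNA quality could both give this, and neither was tested.

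Il7r, Cd28 and Cd4, known from T cells, were present in M0 and lower in M1. T cells in the M0 cultures would carry CD3 chains, but Cd3d, Cd3e and Cd3g together, at 4 counts, came to at most 1.18% of the Cd4 level. Mature T cells are therefore not a likely source, while other cells that express Il7r and macrophages themselves stay open.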
